A study of Rattus norvegicus with 6 samples.

How the data were processed

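Total RNA from the renal cortex of 6 rats was hybridised to 1-colour arrays, 1 array per animal. Per the labels' protocols, RNA was isolated with a Qiagen kit that keeps small RNA, checked on a Bioanalyzer and labelled with Cy3 by linear amplification. Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.1.1 (10.7 per the submitters' processing notes), each array has 62976 spots, and the design is tied to the rat genome build rn4. Per the file headers, the deposited spot intensity used here is a background-subtracted and detrended Cy3 signal. It was taken as not scaled between arrays, because its 75th percentile differed from array to array. The deposited value table holds a linear ratio with no log and no centring per gene. Each of its columns equals the array's own signal divided by that array's 75th percentile, with a ratio of 0.998 between them at values of 1 or more, and the column medians were 0.105, 0.105 and 0.109 for controls and 0.110, 0.108 and 0.108 for treated animals. The labels used here do not state that step, and scale, centring and direction were settled by this comparison.

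Groups and replicate numbers came from the labels. The main values were log2 of the processed signal minus the 75th percentile of each array over its 61537 non-control probes. Spots marked as outliers, 1 to 3 per array, were treated as missing, and no spot was saturated. No 2 arrays shared identical signals. The raw 75th percentile of the signal was 907, 976 and 837 on the control arrays and 1001, 974 and 930 on the treated arrays. The scanner files used here give probe accessions and no gene names. Accessions without versions were matched to a RefSeq gene table of assembly GRCr8, which named 28206 probes of 15645 genes. The other 33331 probes were unnamed and entered no gene-level test. Because rn4 and GRCr8 differ, no coordinates are given.

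Probes were kept where they were well above background on every array of at least 1 group, and a gene with several kept probes was represented by the one with the highest mean. This left 12130 genes, which were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3) and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The prior degrees of freedom were 1.77. Of the genes, 3033 had an unadjusted p under 0.05, and 3981 genes, 32.8%, showed no overlap between groups, where chance gives 10%. A gene below background on all arrays of a group is given as "at least N-fold", the mean of the bright group over that of the dim group after each dim value was raised to the lowest signal of any probe well above background on its array. The 34 gene lists, with 731 genes of which 643 were tested, were compared with other genes by limma's camera with a preset correlation of 0.01. Benjamini-Hochberg adjustment ran over the 34 lists. Beside it stand camera with an estimated correlation, under which none of the 5 list calls held (adjusted p = 0.953), and fry.

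Genes are named in the text by a rule. It takes the 10 largest increases and the 10 largest decreases among called genes with no overlap between groups and an informative name, up to 4 called members of each list with the largest change or, where none was called, the 2 with the smallest p, and Havcr1, Lcn2, Clu, Spp1, Timp1, Cdkn1a, Hmox1, Nqo1 and Mki67 in any case. Exceptions are said to be so. The test was tried on simulated arrays with the means and spreads of the 12130 genes, drawn independently of each other, and 200 changed genes, in 5 draws. It found 92.1% of genes changed 4-fold and 78.1% of those changed 2-fold, with 8.40 false calls among 178 on average. Camera gave an unadjusted p under 0.05 for 5 of 5 simulated lists of 20 raised genes and 0 of 5 lists of 20 unchanged genes. All members of the raised lists were changed 2-fold or 4-fold. The result says nothing of lists with smaller shifts or of lists whose genes vary together.

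The gene lists, the naming rule and the alternatives that follow were fixed before the data were examined. They were a normexp background (offset 50), quantile and median scaling, no filter and a stricter filter on dim probes, the deposited value table, the replicate number as a block, an intensity trend in the variance prior, the mean of a gene's probes, a fold change of at least 2 and leaving out each array. The files hold no mean spot signal, so normexp used the median spot and background signals instead of the planned mean signal. A block for slide or scan could not be fitted, because each of the 2 slides and 2 scans held 1 group. Fits over every probe, without sensory receptor genes, and over genes brighter than the 90th percentile of sensory receptor genes were added after the data were seen.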

Results

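Gene expression was measured in the renal cortex of male Sprague-Dawley rats after 4 weeks of dosing. The comparison asked which transcripts change in the cortex under 4-hydroxy-m-phenylenediammonium dichloride, the dihydrochloride salt of 2,4-diaminophenol, an aromatic diamine that oxidises readily. Control animals received corn oil and treated animals received 100 mg/kg/day of the compound, whose vehicle is not given in the sources used here. Each group held 3 animals, which the design text calls biological replicates, and each animal had 1 Cy3 array of 61537 non-control probes. Of these probes, 66.0%, 67.7% and 63.1% were well above background on the control arrays, and 69.6%, 69.0% and 68.9% on the treated arrays. Correlations between arrays of log2 signal across genes, which are not independent replicates, ran from 0.990 to 0.991 within controls, from 0.993 to 0.994 within treated animals and from 0.985 to 0.991 between the groups. All control arrays lay on slide 1 and all treated arrays on slide 2, scanned separately, so slide and treatment cannot be told apart in any value given here. Levels are log2 signals relative to the 75th percentile of the array, and the number of arrays limits their precision.

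The largest increases among called genes were those of Ugt2b7 and Gstm1. Ugt2b7, a UDP-glucuronosyltransferase, rose from a log2 level of -1.82 ± 0.39 to 4.33 ± 1.49 (SD, n = 3 each), a 70.8-fold difference (log2 fold change 6.15, SE 0.74, limma adjusted p = 0.024). The size depended on single arrays: 43-fold without treated replicate 3 and 121-fold without treated replicate 1. Gstm1, a glutathione S-transferase, rose 14.3-fold from 1.72 ± 0.48 to 5.56 ± 0.40 (log2 fold change 3.84, SE 0.31, adjusted p = 0.014). Among the called genes that fell most were Ppfia4, which encodes a liprin scaffold protein (4.57-fold lower, adjusted p = 0.0493), and Cilp, a matrix protein gene (4.40-fold lower, adjusted p = 0.020). In all, 370 of 12130 genes tested were higher and 161 lower in treated cortex at an adjusted p under 0.05, and 47 and 9 of them differed at least 2-fold in measured signal. The 47 include genes not well above background on any control array, whose bound can be smaller, as for Gata1 (3.33-fold measured, at least 1.098-fold). The higher calls included 41 of a set of 239 olfactory, vomeronasal, taste and trace amine receptor genes, of which none was called lower. The set was taken by gene symbol and singled out after its values were seen. It leaves out olfactory receptor genes with symbols starting with Olr, such as Olr193 and Olr1454, which were both called higher. The mean was higher in the treated animals for 214 of these 239 genes, with a median log2 fold change of 0.40 (0.13 with a normexp background) against -0.030 for all genes tested. In limma fits that left out 1 array, the calls dropped to 0 higher and 0 lower without control replicate 1, control replicate 3, treated replicate 2 or treated replicate 3, to 48 and 6 without control replicate 2, and to 44 and 2 without treated replicate 1, while 2437 to 2647 genes had an unadjusted p under 0.05. The 531 main calls kept their sign and an unadjusted p under 0.05 in each of these fits, which share their arrays with the main fit. Of the calls 69.7% were higher, against 47.2% with a normexp background, which called 459 genes higher and 513 lower.

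**Figure D1:**
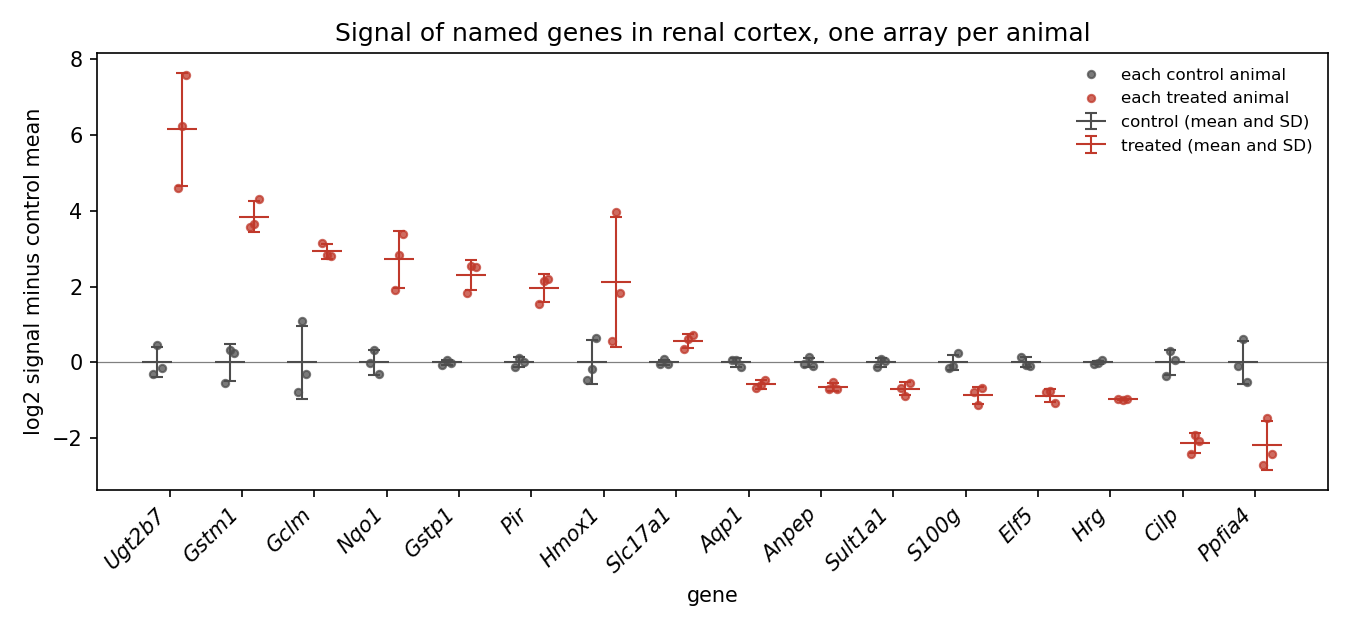
Log2 signal of 16 named genes on each array after subtraction of the control mean, with control animals in grey and treated animals in red. Points are single animals, and bars give the mean and SD of 3 animals. Ugt2b7 (log2 fold change 6.15) and Gstm1 (3.84) lay highest, Hmox1 varied widely between treated animals, and Gclm was not well above background in the controls.

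Targets of NRF2, the transcription factor that answers oxidative and electrophilic stress, rose as a list. Of 38 members tested, 8 were higher, 0 were lower and 30 did not pass over all genes, and 17 were higher and 1 lower when adjusted over the list alone. The median log2 fold change of the list was 0.45 and its shift passed camera with a preset correlation (adjusted p = 6.50e-08). That call was lost when the correlation was estimated (adjusted p = 0.953 with an estimated correlation). Camera with the preset correlation called 5 of the 34 lists between the groups, and up to 13 lists in other splits of the same 6 arrays, and this bears on each list call given here. Nqo1, a quinone reductase, rose 6.58-fold from -2.91 ± 0.32 to -0.19 ± 0.75 (SD, n = 3 each; adjusted p = 0.031). Gstp1, another glutathione S-transferase and already abundant in controls at 5.87 ± 0.06, rose 4.90-fold (log2 fold change 2.29, adjusted p = 0.015), and its other probes had log2 fold changes of 2.97 and 3.12. Gclm, the modifier subunit of the enzyme that starts glutathione synthesis, was not well above background on any control array and was at least 2.81-fold higher in treated animals (adjusted p = 0.037). The other called members were Abcc4, Akr7a3, Ephx1 and Gsta3, named here after their values were seen. Hmox1, which encodes haem oxygenase 1, had a log2 fold change of 2.12 (SE 0.87, adjusted p = 0.206), with treated values from -0.58 to 2.81. Glutathione S-transferase and Ugt2b genes have close relatives within their families, and the values of single members are uncertain to that extent.

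Among cytochrome P450 and conjugating enzymes, 2 of 32 members were higher, 1 was lower and 29 did not pass, and 4 were higher and 3 lower when adjusted over the list alone. Ugt2b37 rose 2.14-fold (adjusted p = 0.032) beside Ugt2b7, and its other probe had a larger log2 fold change of 2.99, whereas the sulfotransferase gene Sult1a1 was 1.62-fold lower (adjusted p = 0.035). Cyp2c11, a cytochrome P450 gene singled out after its values were seen, had a log2 fold change of -2.37 (SE 0.50) that did not pass (adjusted p = 0.060). The list as a whole had a median log2 fold change of -0.028 and did not pass camera (adjusted p = 0.943). Of 4 aryl hydrocarbon receptor targets tested, 1 was higher, Nqo1, and 2 were higher when adjusted over the list alone, while the list did not pass (adjusted p = 0.106). Outside the lists, Pir, which encodes the iron-binding protein pirin, rose 3.88-fold (adjusted p = 0.021). Acta1, skeletal muscle actin, was 4.65-fold higher (adjusted p = 0.039), with only 1 of 3 control arrays well above background. Rgs11, a regulator of G protein signalling, was 3.48-fold higher at its brightest probe (adjusted p = 0.028), while its other probes had log2 fold changes of -0.044 and 0.57. The vomeronasal receptor gene Vom2r12 was 3.55-fold higher (adjusted p = 0.046), with 2 of 3 control arrays well above background.

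The largest decreases among called genes, after Ppfia4 and Cilp, were those of Clec9a, a lectin receptor of dendritic cells (2.76-fold lower, adjusted p = 0.047), and Ten1, a telomere-binding protein gene (2.47-fold lower, adjusted p = 0.038). Dnajc5b, Glyatl1 and Etv4 were 2.45-fold, 2.39-fold and 2.26-fold lower, and Fam3d and Prxl2a 2.13-fold and 2.06-fold lower. Hrg, which encodes histidine-rich glycoprotein, fell from 3.43 ± 0.05 to 2.46 ± 0.01 (SD, n = 3 each), a 1.96-fold difference (adjusted p = 0.013). Among the 16 called named genes with a further probe above background, 2 had such a probe of opposite sign, Rgs11 and Mdm2.

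Genes of fatty acid oxidation and PPAR targets fell as a list, with a median log2 fold change of -0.30 over 32 members (camera adjusted p = 3.75e-04; adjusted p = 0.953 with an estimated correlation). The mean was lower in treated animals for 29 members, but with limma 0 of the 32 passed the gene threshold, over all genes or adjusted over the list alone, and 14 were lower and 1 higher at an unadjusted p under 0.05. Hadhb and Hadh, subunit and enzyme genes of mitochondrial beta-oxidation, had the smallest p, with log2 fold changes of -0.32 (SE 0.08, adjusted p = 0.072) and -0.46 (SE 0.12, adjusted p = 0.083). The list mean relative to controls was -0.19, -0.31 and -0.71 in the 3 treated animals. Genes of proximal tubule metabolism also fell as a list (29 members, median -0.17, camera adjusted p = 0.0434; adjusted p = 0.953 with an estimated correlation), with 24 members lower. With limma 0 of them passed over all genes or adjusted over the list alone, and 8 were lower and 2 higher at an unadjusted p under 0.05. Sardh and Acy3, which encode sarcosine dehydrogenase and an aminoacylase, had log2 fold changes of -0.29 (adjusted p = 0.059) and -0.64 (adjusted p = 0.069). The metabolism list's call was lost without control replicate 1 (adjusted p = 0.174) and without treated replicate 3 (adjusted p = 0.106), and under median, quantile and normexp processing (adjusted p = 0.0565, 0.192 and 0.0656). Set against genes of like signal level, its median was -0.074, where the 1st percentile of random lists was -0.075, and that of fatty acid oxidation -0.22 against -0.069. Mitochondrial respiration and TCA cycle genes did not pass camera, with a median of -0.0036 over 33 members (adjusted p = 0.889), and limma called 0 of them, with 2 higher and 3 lower at an unadjusted p under 0.05. Cox6c and Cox5a, subunit genes of cytochrome c oxidase, had log2 fold changes of -0.18 (adjusted p = 0.0996) and 0.39 (adjusted p = 0.130).

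Within proximal tubule transport and brush border genes, 1 of 39 members was higher, 2 were lower and 36 did not pass, and 1 was higher and 3 lower when adjusted over the list alone. Anpep, the brush border aminopeptidase N, was 1.57-fold lower at 3.66 ± 0.11 against 4.31 ± 0.12 (SD, n = 3 each; adjusted p = 0.030). Aqp1, the water channel of the proximal tubule, was 1.49-fold lower (adjusted p = 0.034). Slc17a1, an apical organic anion transporter gene, was 1.48-fold higher (adjusted p = 0.0496). The list's median of -0.12 did not pass camera (adjusted p = 0.210), although fry, which tests the list alone and not against other genes, gave an adjusted p of 0.0458. An offset between the slides would also move such a test. Spike-in transcripts had a median log2 difference of -0.13 after the same scaling, and quantile scaling took the list's median to -0.070. Whether such an offset accounts for the fry result was not tested. The brush border list was the only one of the 34 lists to pass fry's test of a shift in one direction, whose adjusted p for the 5 lists called by camera was 0.1 for NRF2 targets, 0.149 for red blood cell genes, 0.232 for fatty acid oxidation, 0.215 for cell cycle and 0.190 for proximal tubule metabolism. Fry's test of change in either direction, which most lists passed, gave those lists an adjusted p of 0.00327, 0.0202, 0.0411, 0.00137 and 3.40e-04 in the same order. Beyond the proximal tubule, S100g, the calcium-binding protein of the distal convoluted and connecting tubule list, was 1.83-fold lower (adjusted p = 0.044), and Elf5, a transcription factor of principal cells, was 1.83-fold lower (adjusted p = 0.028). Each was the only called member, of 7 and 11 tested, 1 and 3 members were lower when adjusted over the list alone, and neither list passed camera (adjusted p = 0.184 for both).

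Red blood cell genes rose as a list of 8 members with a median log2 fold change of 1.35, or 0.85 with a normexp background (camera adjusted p = 2.07e-05; adjusted p = 0.953 with an estimated correlation). All 8 had higher values in every treated animal than in any control animal. Of all genes tested, 32.8% showed no overlap between the groups in either direction, where chance gives 10%. Over all genes 1 member was called, and 8 were higher when adjusted over the list alone. The called gene was the erythroid transcription factor Gata1, which was not well above background on any control array and was at least 1.098-fold higher (adjusted p = 0.039), and with Gata1 at this bound the list's median was 0.99. Slc4a1, the anion exchanger of red cells and intercalated cells, had a log2 fold change of 0.40 (SE 0.09, adjusted p = 0.072). The list mean relative to controls was 0.64, 1.52 and 1.67 in the 3 treated animals. The same animals had NRF2 list means of 0.55, 0.89 and 0.84. Leukocyte markers did not shift as a list (14 members, median -0.11, adjusted p = 0.801), and limma called 0 of them, with 1 higher and 2 lower at an unadjusted p under 0.05. Within it, Cd52, a surface glycoprotein of lymphocytes, had a log2 fold change of 2.41 (SE 0.57, adjusted p = 0.073) and Coro1a one of -0.32 (adjusted p = 0.148).

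**Figure D2:**
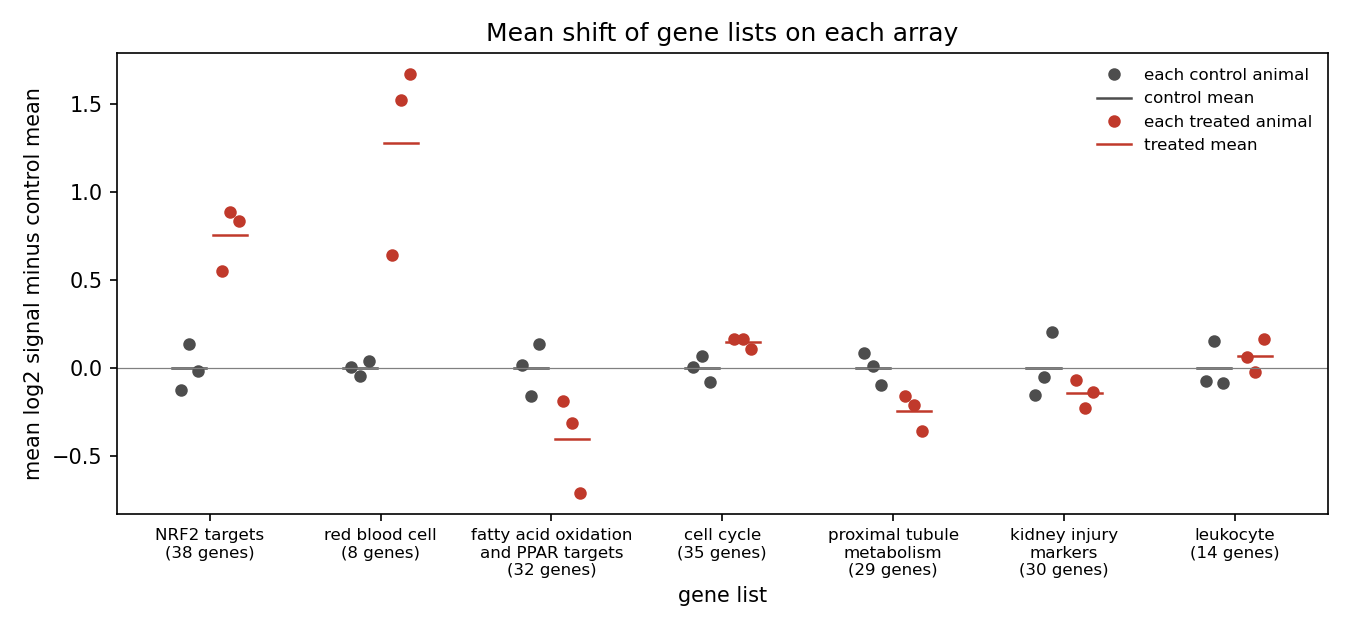
Mean log2 signal of the members of 7 gene lists on each array, relative to the mean of the control arrays. Points are animals and lines are group means of 3 animals. Red blood cell genes lay at 0.64 to 1.67 in treated animals, NRF2 targets at 0.55 to 0.89, and fatty acid oxidation and PPAR targets at -0.71 to -0.19.

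Cell cycle genes rose slightly as a list (35 members, median log2 fold change 0.14, camera adjusted p = 0.00422; adjusted p = 0.953 with an estimated correlation). Of the members 1 was higher over all genes and 3 were higher when adjusted over the list alone. The called gene was Cdc20, an activator of mitotic exit, at 1.26-fold (adjusted p = 0.045), while Mki67, the proliferation antigen, had a log2 fold change of 0.023 (SE 0.060, adjusted p = 0.845) at its brightest probe and of 0.11 to 0.41 at the other 4. The cell cycle call was lost without control replicate 3 (adjusted p = 0.0959). Set against genes of like signal level, the list's median was 0.15, where the 99th percentile of random lists was 0.10 and the highest 0.17. The sensory receptor genes lay 0.34 above other genes of like level, a larger rise. Of 22 p53 targets, 1 was higher and none lower over all genes, and 2 were higher and 2 lower when adjusted over the list alone. The called gene was Mdm2, the p53 ubiquitin ligase gene, at 1.38-fold (adjusted p = 0.046), although its other probe had a log2 fold change of -0.025. Cdkn1a, the p21 inhibitor gene, had a log2 fold change of 0.35 (SE 0.09, adjusted p = 0.084) at its brightest probe and -0.24 and -0.12 at the others. The p53 list had a median of 0.052 and did not pass camera (adjusted p = 0.801).

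Kidney injury markers did not shift as a list (30 members, median log2 fold change -0.087, camera adjusted p = 0.801), and with limma 0 members were called over all genes or adjusted over the list alone, with 2 higher and 4 lower at an unadjusted p under 0.05. Havcr1, which encodes kidney injury molecule 1, had a log2 fold change of 0.66 (SE 0.52, adjusted p = 0.475). Lcn2, Clu and Timp1 had log2 fold changes of -0.95 (SE 0.86), -0.39 (SE 0.36) and -0.16 (SE 0.084), none past the threshold. Spp1, the osteopontin gene, had a log2 fold change of 0.70 (SE 0.19, adjusted p = 0.101), with no overlap between the groups. The smallest p in the list belonged to Krt7 and Anxa1, with log2 fold changes of -0.28 (adjusted p = 0.055) and -0.26 (adjusted p = 0.085).

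The remaining lists did not pass camera (adjusted p from 0.189 to 0.932). Single members were called in 8 of them. Those called higher, like Cdc20 and Mdm2 above, had log2 fold changes below 1.56, the 99th percentile of the sensory receptor genes. By size alone they cannot be told from the rise of those genes on the treated slide. Nos2, the inducible nitric oxide synthase among 30 inflammatory mediators, was 1.90-fold higher (adjusted p = 0.014). Acta2, smooth muscle actin, which belongs to both the extracellular matrix list (28 members, median -0.16) and the smooth muscle and juxtaglomerular list (10 members, median 0.013), was 1.42-fold higher (adjusted p = 0.039). Of 15 circadian clock genes, 1 was higher and 14 did not pass, with 4 higher and 4 lower at an unadjusted p under 0.05. Per3 was the called member, at 1.63-fold (adjusted p = 0.039). Further members, named after their values were seen and not past the threshold, were Nr1d1 (log2 fold change 1.51) and Nr1d2 (0.67) on the one side and Nfil3 (-1.32), Bmal1 (-1.11), Cry1 (-1.05) and Npas2 (-0.87) on the other, with adjusted p from 0.064 to 0.239. Lpl of the adipose tissue list (7 members) was 1.51-fold higher. Fdft1, squalene synthase, of 24 cholesterol synthesis genes and Chac1 of 27 unfolded protein and amino acid response genes were both 1.27-fold higher, and the other probe of Chac1 had a log2 fold change of 1.41 against 0.34. Of 22 iron and haem genes only Urod, an enzyme of haem synthesis, was called over all genes, and it was 1.32-fold lower (adjusted p = 0.030). No member was called in the lists of podocyte, endothelium, thick ascending limb, intercalated cell, macrophage, T cell and B cell markers, whose medians ran from -0.16 to 0.053, while at an unadjusted p under 0.05 limma gave at most 2 higher and at most 2 lower in each of them. The macrophage lectin gene Clec7a had the smallest p among macrophage markers (log2 fold change -0.33, adjusted p = 0.059), and the loop of Henle protein gene Umod had a log2 fold change of -0.34 (SE 0.18, adjusted p = 0.292). The same held for heat shock and metallothionein genes, where the metallothionein gene Mt1 had a log2 fold change of -0.61 (SE 0.12, adjusted p = 0.052), and for glucocorticoid targets, interferon response genes, immediate early genes and renin-angiotensin and prostaglandin genes, with at most 3 higher and at most 3 lower in each at an unadjusted p under 0.05. Their medians ran from -0.066 to 0.041. Adjusted over the list alone, 2 smooth muscle and juxtaglomerular members were higher, 1 extracellular matrix member was higher and 2 lower, 1 member was higher and 1 lower in both the circadian clock and the iron and haem list, and 1 heat shock and metallothionein member was lower. The other lists of this group had the same counts as over all genes. The sign of the median turned with the scaling or background in the smooth muscle, intercalated cell, endothelium, mitochondrial, interferon and unfolded protein lists. Median, mean and camera's direction differed in sign in the adipose tissue, leukocyte, inflammatory mediator, mitochondrial, interferon, immediate early, unfolded protein, renin-angiotensin and cytochrome lists.

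**Figure D3:**
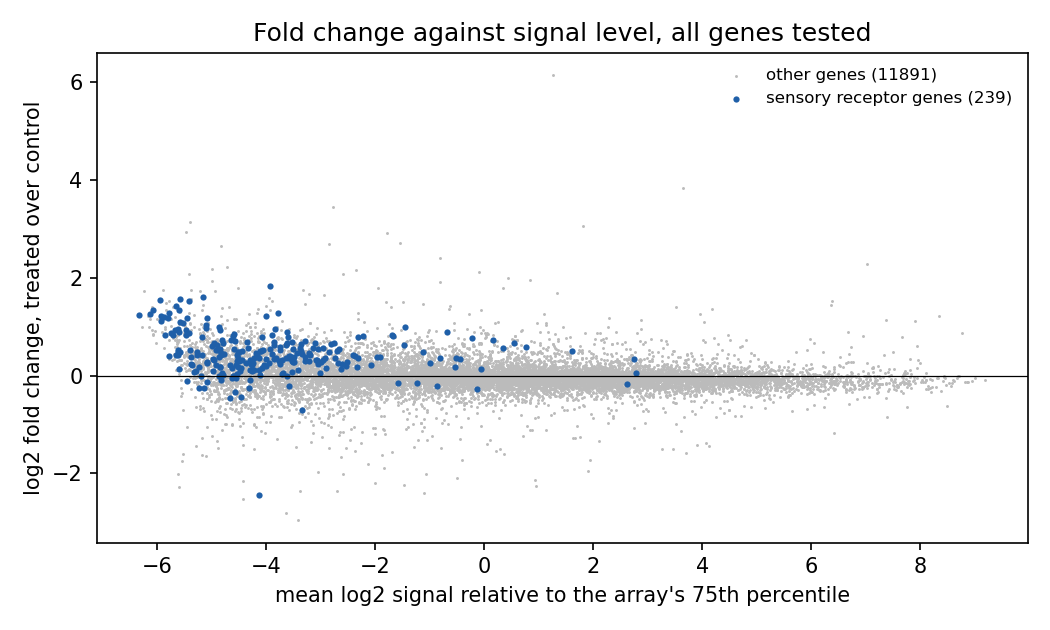
Log2 fold change of treated over control against the mean log2 signal of each of 12130 genes, with 239 sensory receptor genes in blue and the other 11891 genes in grey. Most sensory receptor genes lay above 0, with a median of 0.40, and most had low signals.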

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

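The probe-level test of unnamed probes was chosen after the data had been seen. The report's comparisons use named genes, and signals also differed among probes that matched no gene in the reference. Of 19882 such probes kept by the same background filter, 1596 were higher and 452 were lower in treated cortex with limma at an adjusted p under 0.05. The largest increases were those of probes C_CA_F0069 (log2 fold change 6.22, adjusted p = 0.00648) and A_44_P347283 (5.52, adjusted p = 0.0149, with 1 of 3 control arrays well above background), and the largest decrease that of A_44_P651881 (-1.99, adjusted p = 9.57e-04). The files do not pair these probes with gene names.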

How the results depend on the processing

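Fits over every probe, without sensory receptor genes, and above the sensory receptor level were chosen after the data were seen. Counts of higher and lower genes were 370 and 161. They stayed within 1.5 times under quantile (329 and 122) and median scaling (276 and 140), the deposited table (372 and 161) the filter on all 6 arrays (373 and 209), and without sensory receptor genes (315 and 153). They moved to 37 and 7 with no filter on dim probes (15645 genes), 229 and 63 for the mean of a gene's probes, 47 and 9 with a fold change of at least 2, which removes calls by construction, and 2039 and 715 over every probe. There more features were tested, and unnamed probes were called in larger shares than named genes (1596 and 452 of 19882, against 370 and 161 of 12130). Lower genes alone moved to 513 with normexp, 395 with the intensity trend and 404 above the sensory receptor level. Except for the fold setting, the cause was not tested. Without 1 array the counts ran from 0 to 48 and from 0 to 6, with fewer samples in each fit. The genes and their probes were held fixed in these fits. With the replicate block limma called 0 and 0, with 2547 genes at an unadjusted p under 0.05. Residuals of same-numbered animals correlated at -0.12, -0.11 and 0.09, so the numbers do not pair the animals, and not every animal correlated best with its own number. A slide or scan block could not be fitted. Of the 5 called lists, NRF2 targets, red blood cell genes and fatty acid oxidation kept direction and call under every alternative run on lists except an estimated correlation (a fold change of at least 2, every probe, and leaving out sensory receptor genes were run on gene counts only), under which 0 lists passed, with medians still 0.45, 1.35 (0.85 with normexp) and -0.30 (cell cycle 0.14, proximal tubule metabolism -0.17). Over all alternatives but left-out arrays, the adjusted p of NRF2 targets ran from 8.50e-11 to 0.953, of red blood cell genes from 2.65e-06 to 0.953, of fatty acid oxidation from 1.23e-04 to 0.953, of cell cycle from 2.21e-04 to 0.953 and of proximal tubule metabolism from 0.0126 to 0.953. Proximal tubule metabolism lost its call with normexp (-0.18), quantile (-0.14) and median scaling (-0.20), and with no filter, the stricter filter and the sensory receptor level (each -0.17), the cause not tested. Without 1 array its median ran from -0.23 to -0.14 and that of cell cycle from 0.11 to 0.18. Of 29 uncalled lists, 7 of 493 list and setting pairs passed, and camera's sign turned in 42. Mki67, not called, turned to -0.089 with normexp and -0.010 with median scaling, and ran from -0.0045 to 0.059 without 1 array. Cdkn1a turned to -0.0051 for the mean of its probes, and Lcn2 ran from -1.62 to 0.053 without 1 array. The cause was not tested. The other values of single named genes kept direction, 875 on the same side of the threshold, 296 losing it and 29 passing it. Signal over background limits the dimmest genes. Of each 1213 genes by level, 48 were called higher and 3 lower among the dimmest, 59 and 10 among the next, and 15 and 37 among the brightest.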

Other observations

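The tests of brightness, of further probes, of the scaling of sensory receptor genes and of other splits by gene counts were chosen after the results were seen, as were the set of sensory receptor genes and the weight given to S100a8 and S100a9. Of 22 erythroid genes outside the fixed list, 19 had a higher mean in treated animals, 4 were called higher with limma and 18 did not pass. Those called included Nfe2 (log2 fold change 1.41, SE 0.25, adjusted p = 0.044), Trim58 (0.86, SE 0.11, adjusted p = 0.027) and Slc25a37 (0.29, SE 0.05, adjusted p = 0.049). These genes were named after their values were seen. The spike-in transcripts, added in equal amounts by the labelling kit's design, were slightly lower on the treated slide after scaling, with a median log2 difference of -0.13 and a range from -0.19 to -0.065 over the 7 spike-ins well above background on all their spots.

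The rise of NRF2 targets was set against technical explanations. A rise of all probes of like brightness is argued against. The list lay a median of 0.51 above genes of the same level, beyond the 99th percentile of 0.071 for 10000 level-matched random lists. Sensory receptor genes too lay a median of 0.34 above other genes of the same level. The comparison therefore cannot speak to a slide effect limited to certain genes. An artefact of single probes is argued against for the members with another probe. Those probes had a median log2 fold change of 0.47 (SE 0.18), with 34 of 38 higher. The 38 probes belong to 21 genes measured on the same 6 arrays, 4 of them among the 8 called members. The called members Gstm1, Gclm, Akr7a3 and Ephx1 had 1 kept probe each, as did Ugt2b7, so the test does not cover them. SEs of medians in this section are taken over probes or genes and do not measure spread between animals. A slide or processing batch stays open, because 0 slides held arrays of both groups, and treatment and slide cannot be told apart. A response of the tissue to the compound is a hypothesis that no value here separates from that batch.

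Sensory receptor genes, most of them not known for a role in kidney, were higher on the treated slide. The choice of scaling, which moves genes of like level alike, is argued against, since the 239 genes lay a median of 0.34 (SE 0.036) above other genes of the same level. An added background of equal size for every probe is argued against, since the 120 brighter genes had a median log2 fold change of 0.37 (SE 0.048), 0.865 times the 0.43 of the 119 dimmer genes, where an equal addition would leave the brighter ones at 0.14. With normexp, which took median spot signals, another background correction and an offset together, the median was 0.13 instead of 0.40 and 82.4% of the genes were higher, and which of these choices lowered it was not tested. A slide or labelling batch (0 slides with both groups) cannot be told apart from treatment, and may account for part of the 370 higher calls, of which 329 lay among the 11891 other genes, with Olr193 and Olr1454 among the 329.

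Red blood cell genes rose in the treated cortex by a median of 1.35. A rise of all probes of like brightness is argued against. The list lay 1.39 above genes of the same level, against a 99th percentile of 0.19 for random lists. As for NRF2 targets, the comparison cannot speak to a slide effect limited to certain genes. More blood of ordinary make-up left in the tissue stays open: neutrophil and platelet genes had a median of 0.31 (SE 0.22), below the bound of 0.68 set beforehand, but that bound was wrong for a list whose members went both ways, since 9 of the 13 were higher and the abundant neutrophil transcripts S100a8 and S100a9 had log2 fold changes of 1.51 and 1.35, against 0.88 for Hba-a1 and 0.80 for Hbb. More immature red cells in the treated animals is a candidate explanation. The 22 other erythroid genes gave a camera p of 1.02e-06 before adjustment with the preset correlation, which the called lists did not survive without. More blood in the tissue or a slide batch could raise these genes too, so their rise does not separate the explanations. Slide or processing batch instead of treatment (0 slides with both groups) stays open too.

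Other splits of the 6 arrays were counted for both kinds of result. The real split called 531 genes and the highest of the other 9 splits 1, and 1 of the 10 splits, the real one, gave as many. For gene lists the real split called 5 and the highest other split 13, and 7 of the 10 splits gave as many. Both have too few splits for a share under 0.05. Each other split set arrays of both groups on each side, so a difference between the groups would widen its spread and lower its gene calls. The gene counts of the other splits are therefore no measure of what chance gives. The split that called 13 lists set control replicate 1 with treated replicates 2 and 3, and no value here separates a structure among the animals from treatment or from the preset correlation. Camera's unadjusted p was as small or smaller in 2 of 10 splits for NRF2 targets and cell cycle, in 3 for fatty acid oxidation and for proximal tubule metabolism, and in 1, the real split, for red blood cell genes.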
